A study of Mus musculus with 14 samples.

How the data were processed

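RNA was measured in 12 bulk libraries of mouse liver, 3 replicates in each of 4 groups, and in 2 single-nucleus libraries that each pool nuclei of 3 livers. Processing notes of the submitters name FastQC, STAR and DESeq2 for bulk libraries and Cell Ranger and Seurat 4.0.1 for nuclei, on genome build mm10; other versions, the annotation and the read counter are not given. Groups follow the labels. The table whose columns carry the labels wild type and KO was named for lipid droplets by the submitters, and the table whose columns carry the labels PBS and LD was named for Ms4a7, so the labels and the table names disagree. Comparisons keep the labels, and the closing section weighs the disagreement.

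The bulk signal values were made by the authors as gene counts divided by a DESeq2-style size factor per library, as deposited. This was read from the values: in each of the 12 libraries 100% of values were whole multiples of 1 step within a tolerance of 0.01, so that whole reads could be recovered. The deposited log2 fold changes were made by the authors between the groups, with DESeq2 per their processing notes. The deposited p values and adjusted p values were made by the authors, with DESeq2 per the same notes. What made a further q value in the table labelled wild type and KO is not stated. The deposited single-nucleus signal values were made by the authors as the mean, over the nuclei of a numbered group and genotype, of UMIs scaled to 10000 per nucleus. The 2 bulk tables were scaled separately, held 23404 and 20337 genes, and shared 17582 symbols, so fold changes were compared only within a table unless stated. The size factors computed here were 1.21 to 1.23 times the deposited ones for the table labelled wild type and KO. For the other table they were 1 time the deposited ones. The factor is nearly constant, so that it nearly cancels within a table.

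Recovered reads in genes ran from 21945394 to 23126164 per library in the table labelled wild type and KO and from 39318264 to 41346464 in the other, with 17.2% to 20.3% and 23.9% to 26.4% of them in the leading 10 genes. The gap between replicates was at least 18.3 times counting error (chi-square per degree of freedom), so replicates are separate libraries and not copies. The 1 counting interval given is exact (Clopper-Pearson on the split of reads, 95%) and covers counting error only, since reads carry no molecular identifiers. Depth of the nuclei is unknown, so no interval is given for them.

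Genes with at least 10 normalized counts in 3 or more of the 6 libraries of a table were tested with limma 3.58.1 (lmFit and eBayes with trend, 2-sided) on log2 of the value plus 1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used, since labels give none. The choice of test, thresholds, 37 gene lists, marker genes and the rule for named genes were fixed before the data were examined. The rule names Ms4a7, the 10 largest changes per direction past the threshold with a mean of at least 50 and groups that do not overlap (leaving out Gm and Rik models), the leading 2 to 4 called members of each list, and up to 5 genes per direction called alike in both comparisons. In nuclei it names 5 genes per direction and group among the top 2000 by level, with Ms4a7, Trem2 and Gpnmb. The 37 lists cover macrophage and other cell types, fibrosis, the NLRP3 inflammasome, cytokines, receptors, the acute phase, interferon, lipid, bile acid, xenobiotic and glucose metabolism, the lysosome, cell cycle, stress, clock, sex, blood, adipose, pancreas, mitochondrial and immediate early genes, and the MS4A cluster without Ms4a7. They were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Positions come from GENCODE annotation of mm10, and LOC118567843 and Urml have none in it.

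Overlap of calls was tested with Fisher's exact test, which takes genes as independent. For nuclei, log2 ratios of KO to wild type were taken over genes above the 50th percentile of level in a group, with a pseudocount at the 5th percentile of values above 0. The median of a list was placed among 10000 random lists of the same size and level, and medians outside percentiles 2.5 to 97.5 are called outside the central 95%. Groups of nuclei are numbered in the table, without names. The rule that named them was set after the table was examined: at least 3 markers of a type at 0.5 or more of the highest group's level, a share of its markers at least 2 times that of the next type, and a gene of that type among the leading 10. A first, rank-based rule had left the groups now called macrophage-like, neutrophil-like, T or NK cell-like and dendritic cell-like unnamed and had called a group cholangiocyte-like that is now unnamed. The present rule names 10 groups and leaves 2 unnamed, and 4 table entries with a repeated gene name were left out. The labels do not say how doublets were treated, and no caller was run, since the table holds means and not nuclei.

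The other settings tried were quantile normalization, DESeq2 1.42.0 on recovered reads, no filter, a mean of at least 50, a pseudocount of 5, a minimum log2 change of 1, a replicate block, and leaving out each library. Settings chosen after seeing the data were edgeR 4.0.16 quasi-likelihood on recovered reads and TMM scaling. DESeq2 run here called the same 1193 genes that the deposited table labelled PBS and LD holds at its threshold. For the table labelled wild type and KO it called 1244, while the deposited adjusted p values give 2683, of which 1214 are shared. Other filters and fits tried informally did not recover the 2683 either, and the cause was not tested. Methods were tested on simulated data with 200 changed genes, all drawn from genes with a mean of at least 50. Recovery of genes below that level was therefore not tested. The simulated spread followed the trend over level and not the spread of each gene. For KO against wild type (15557 genes) limma recovered 79% of those changed 2-fold and 100% of those changed 4-fold, with 12 of 193 calls false, against 13 of 196 in edgeR and 28 of 212 in DESeq2. For LD against PBS (14691 genes) limma recovered 89% and 100%, with 5 of 198 calls false, against 7 of 203 in edgeR and 5 of 201 in DESeq2. In both, camera called a list shifted by 0.5 and 0 of 30 unshifted lists, on genes simulated without correlation. That leaves its calls on correlated genes untested. Of 100 simulated unshifted lists in the second hepatocyte-like group of nuclei, 4 fell outside the central 95%, and 100 of 100 lists shifted by 1 log2 unit did. The unshifted lists were drawn at random from the genes that form the reference, so a small share outside follows by construction. Lists of genes that move together and smaller shifts were not tested. Python 3.11.15 with NumPy 2.4.6 handled the nuclei, and Matplotlib 3.10.9 drew the figures.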

Results

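Liver RNA of mice was measured in 12 bulk libraries and 2 single-nucleus libraries. The bulk libraries form 4 groups of 3 replicates: wild type and Ms4a7 knockout (KO) mice on a diet that induces nonalcoholic steatohepatitis (NASH) for 22 weeks, and mice with healthy livers given phosphate-buffered saline (PBS) or lipid droplets (LD) for 6 days. Each single-nucleus library pools nuclei of 3 livers of 1 genotype on the NASH diet. Ms4a7 encodes a membrane protein of macrophages in the MS4A family, and Trem2 marks the lipid-associated macrophages that the series title names. The table labelled wild type and KO held 21945394 to 23126164 gene reads per library, and the table labelled PBS and LD held 39318264 to 41346464. Replicate errors are SD with n = 3 libraries, and fold changes are log2 values ± SE from limma.

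The level of Ms4a7 (mm10 chromosome 19, 11321039 to 11336146, minus strand) went against the genotype labels of the bulk libraries. It was 19.6 ± 8.67 normalized counts (SD, n = 3) in the libraries labelled wild type and 118 ± 17.0 in those labelled KO, a log2 fold change of 2.63 ± 0.37 (adjusted p = 0.0149). All 3 libraries labelled KO lay above all 3 labelled wild type. The call ended when KO replicate 2 or 3 was left out, at an adjusted p of up to 0.063. In the other table Ms4a7 was 103 ± 52.9 in the libraries labelled PBS and 9.14 ± 1.46 in those labelled LD, a change of -3.26 ± 0.39 (adjusted p = 0.00428). That call held without any 1 of the 6 libraries. Groups are therefore named below as "labelled KO", "labelled LD" and so on, and each direction holds for the libraries that carry the label, whatever the animal.

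**Figure D1:**
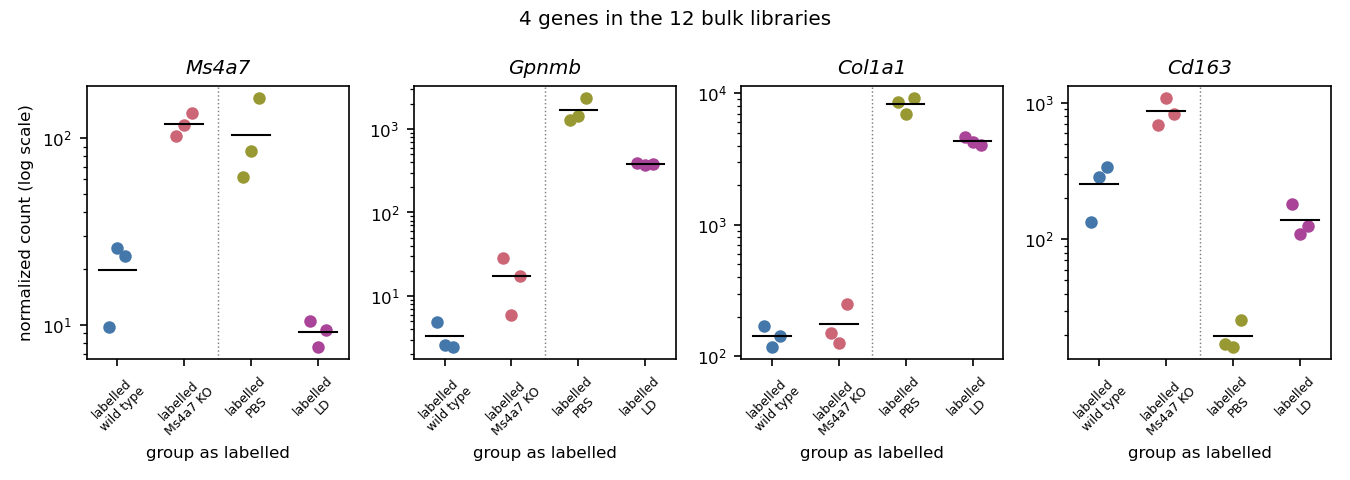
Normalized counts (log scale) of Ms4a7, Gpnmb, Col1a1 and Cd163 in the 12 bulk libraries, by group as labelled; points are libraries, bars are group means, and the dotted line parts the separately normalized tables. Ms4a7 averaged 118 in the libraries labelled KO and 9.14 in those labelled LD, and Gpnmb averaged 3.29 in the libraries labelled wild type and 1670 in those labelled PBS.

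By its labels, the first comparison asks which liver transcripts differ with loss of Ms4a7 on the NASH diet. Macrophage and inflammatory transcripts were higher in the libraries labelled KO. Cxcl13 (chromosome 5, 95956951 to 95961068), a chemokine that attracts B cells, went from 53.6 ± 28.7 to 12760 ± 4730 normalized counts, a log2 fold change of 7.92 ± 0.42 (adjusted p = 0.0017). Marco (chromosome 1, 120474538 to 120505024), a scavenger receptor of resident macrophages, went from 404 ± 143 to 14120 ± 4250, a change of 5.15 ± 0.33. Lyz2 (chromosome 10, 117277331 to 117282321), the lysozyme of myeloid cells, went from 804 ± 172 to 13390 ± 4091, a change of 4.03 ± 0.25. Hepatocyte transcripts were among those that fell: Mup9, a major urinary protein gene whose reads can be shared with its close copies, went from 27970 ± 8242 to 5994 ± 2397, a change of -2.24 ± 0.31 (adjusted p = 0.0147).

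Of 15827 genes tested, 589 passed in the libraries labelled KO against those labelled wild type. Of these, 478 were higher and 111 lower, so 81.2% were higher, and 405 rose and 45 fell by at least 1 log2 unit. At an unadjusted p under 0.05 there were 2960 genes. The 3 values of a group lay apart from the 3 of the other for 24.2% of genes, where chance gives 10%. Further genes with the largest rises within the rule for named genes were Chil1, a chitinase-like protein (6.25 ± 0.73), the hexose transporter Slc2a6 (5.56 ± 0.42), Ppm1n (4.94 ± 0.50), the monocyte attractant Ccl2 (4.39 ± 0.34), Procr (3.91 ± 0.46) and Dram1 (3.89 ± 0.38). Acod1, which makes itaconate in activated macrophages, had 3 reads in the libraries labelled wild type and 679 in those labelled KO, a ratio of 216 with a counting interval of 73.7 to 1050 (95%, exact). Within the rule for named genes, the largest falls were in Mup-ps4 (-3.27), Krt23 (-3.16), Cxcl9 (-2.81), Gbp2b (-2.55), Cyp8b1 (-2.48), Onecut1 (-2.45), Mup-ps10 (-2.40), Mup9, Gadd45g (-2.01) and the guanylate-binding gene Gbp11 (-1.86 ± 0.15). The calls of Mup9 and Gbp11 held without any 1 library. Each of the other 8 was lost in at least 3 of the 6 fits without 1 library, with adjusted p up to 0.128, and the call of Cyp8b1 was also lost in edgeR.

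**Figure D2:**
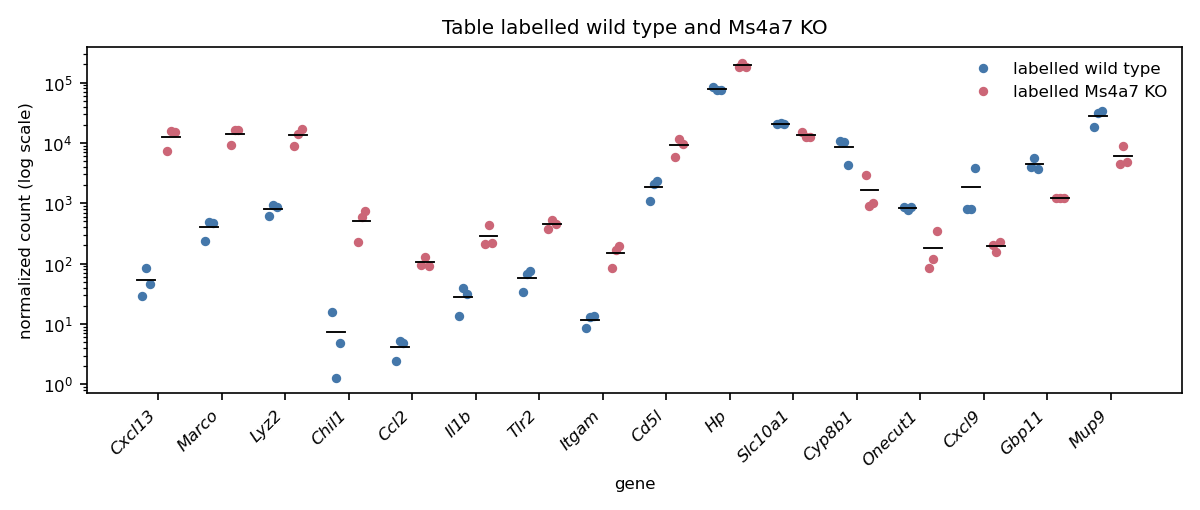
Normalized counts (log scale) of 16 named genes in the 6 libraries labelled wild type or KO; points are libraries and bars are means of 3. Cxcl13 averaged 53.6 and 12760, Lyz2 804 and 13390, and Gbp11 4491 and 1220 in the libraries labelled wild type and KO.

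Myeloid lists rose together in the libraries labelled KO. Of 15 markers of monocytes and recruited macrophages, 8 rose and 7 did not pass (13 rose adjusted over the list alone). The camera adjusted p was 1.53e-11, and the adjusted p = 0.157 with an estimated correlation. Itgam, an integrin of myeloid cells, rose by 3.52 ± 0.36 and the endotoxin co-receptor Cd14 by 2.39 ± 0.26, both without exception when 1 library was left out. Of 13 resident Kupffer cell markers, 4 rose and 9 did not pass (7 rose adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.423 with an estimated correlation). Besides Marco these were Timd4, which binds phosphatidylserine on dying cells (2.47 ± 0.33), Cd5l (2.33 ± 0.33) and the haemoglobin scavenger receptor Cd163 (1.86 ± 0.34). Of 14 lipid-associated macrophage markers tested, 6 rose and 8 did not pass (10 rose adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.157 with an estimated correlation). Lgals3, a galectin, rose by 1.96 ± 0.27 and Tyrobp, the signalling partner of TREM2, by 1.69 ± 0.33. The 2 remaining members of that list, Trem2 and Gpnmb, were too low to test: Trem2 was 2.08 ± 0.756 and 15.3 ± 5.46 normalized counts in the libraries labelled wild type and KO, and Gpnmb 3.29 ± 1.35 and 17.2 ± 11.2. Of 17 genes of the MS4A cluster around Ms4a7, 4 rose and 13 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.000649, adjusted p = 0.335 with an estimated correlation). Among them were Ms4a6c (2.5 ± 0.35) and Ms4a6d (2.51 ± 0.44), close copies that can share reads.

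Inflammatory lists moved the same way. Of 15 cytokines and chemokines, 11 rose, 1 fell and 3 did not pass (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.16e-09, adjusted p = 0.157 with an estimated correlation). The neutrophil attractant Cxcl1 rose by 2.85 ± 0.20 and the macrophage growth factor Csf1 by 1.63 ± 0.14, while Cxcl9, an interferon-induced attractant of T cells, is the member that fell. Of 16 genes of the NLRP3 inflammasome, 5 rose and 11 did not pass (11 rose adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.157 with an estimated correlation). Il1b (chromosome 2, 129364570 to 129371139), the precursor of a secreted inflammasome product, went from 28.4 ± 13.7 to 288 ± 122 normalized counts (3.35 ± 0.44, adjusted p = 0.0122), and Il18 rose by 0.77 ± 0.10. Il1a (1.74 ± 0.26), the receptor antagonist Il1rn (1.27 ± 0.21) and Nlrp3, named here after its values were seen (2.23, adjusted p = 0.0329), also rose. Of 13 danger and lipid receptors, 4 rose and 9 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.06e-06, adjusted p = 0.22 with an estimated correlation). Tlr2, which senses bacterial lipoproteins, rose by 2.98 ± 0.30 and the receptor kinase Axl by 1.54 ± 0.31. Of 18 acute phase genes, 2 rose and 16 did not pass (2 rose adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.67 with an estimated correlation): haptoglobin Hp (1.30 ± 0.17) and haemopexin Hpx (1.06 ± 0.19). Of 20 interferon response genes, 2 rose and 18 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.525 with an estimated correlation). Among them was the guanylate-binding gene Gbp2 (2.23 ± 0.36). Of 13 immediate early genes, 5 rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000521, adjusted p = 0.157 with an estimated correlation). Fos rose by 2.10 ± 0.33 and Junb by 1.19 ± 0.21.

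Lists of p53 and cell death, the cell cycle, the lysosome and fibrosis, and of B and plasma cells, were also higher in the libraries labelled KO. Of 14 p53 and cell death genes, 2 rose and 12 did not pass (9 rose adjusted over the list alone, camera adjusted p = 8.5e-07, adjusted p = 0.157 with an estimated correlation). Those were the BH3-only gene Pmaip1 (2.76 ± 0.35) and the necroptosis kinase Ripk3 (2.32 ± 0.39). Of 19 cell cycle genes, 2 rose and 17 did not pass (4 rose adjusted over the list alone, camera adjusted p = 7.37e-06, adjusted p = 0.157 with an estimated correlation): the proliferation marker Mki67 (1.60 ± 0.26) and the cyclin Ccnd1 (1.59 ± 0.26). Of 20 lysosomal genes, 5 rose and 15 did not pass (8 rose adjusted over the list alone, camera adjusted p = 8.95e-05, adjusted p = 0.335 with an estimated correlation). They included progranulin Grn (0.82 ± 0.12) and the myeloid transcription factor Tfec (2.02 ± 0.40). Of 16 fibrosis and extracellular matrix genes, 1 rose and 15 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000416, adjusted p = 0.423 with an estimated correlation). The riser was the growth factor Tgfb1 (1.66 ± 0.31), not a matrix protein. Of 10 B and plasma cell markers, limma and edgeR called 0 and DESeq2 2, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone; the list median was 1.09 (camera adjusted p = 0.0107, adjusted p = 0.59 with an estimated correlation).

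Hepatocyte programmes made up the lists that were lower in the libraries labelled KO. Of 16 genes of bile acid synthesis and transport, 2 fell, 1 rose and 13 did not pass (4 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.22 with an estimated correlation). The bile acid uptake transporter Slc10a1 fell by 0.65 and the sterol hydroxylase Cyp8b1 as above, while Nr0b2, a repressor of bile acid synthesis, rose by 0.86 ± 0.16. Of 22 genes of fatty acid oxidation, Cpt2 fell (-0.53 ± 0.11; lost in edgeR, which called 0, with quantile normalization and without a filter) and 21 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.423 with an estimated correlation). Of 14 sex-biased or sex chromosome genes, Elovl3 (-1.37 ± 0.27) and Cyp4a12a (-0.65 ± 0.13) fell and 12 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.000545, adjusted p = 0.157 with an estimated correlation). Limma and edgeR called 0 of 17 lipid droplet protein genes and 0 of 22 of xenobiotic metabolism, DESeq2 4 of each, with 8 and 7 at an unadjusted p under 0.05. Adjusted over the list alone, 5 fell and 1 rose in the lipid droplet list (camera adjusted p = 0.00284, adjusted p = 0.157 with an estimated correlation) and 0 in the xenobiotic list (camera adjusted p = 0.0167, adjusted p = 0.525 with an estimated correlation). The 15 general hepatocyte markers gave 0 calls in limma, 1 in edgeR and 2 in DESeq2, with 2 at an unadjusted p under 0.05, 0 adjusted over the list alone, a median of 0.01 and a test direction of the other sign (camera adjusted p = 1).

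The other 13 lists tested did not pass in this comparison. In the list of sinusoidal endothelium Cdh5 rose by 1.60 ± 0.34 (1 of 14, 1 adjusted over the list alone, camera adjusted p = 0.166). In that of glucose production Pck1 rose by 1.21 ± 0.25 (1 of 12, with 1 up and 1 down adjusted over the list alone, camera adjusted p = 0.959). Limma called 0 members of the lists of hepatic stellate cells (camera adjusted p = 0.0525), dendritic cells and MHC class II (0.0627), cholangiocytes (0.0627), NRF2 and oxidative stress (0.389), fatty acid synthesis (0.414), mitochondrially encoded transcripts (0.498), cholesterol synthesis (0.688), and red blood cells, T and NK cells, the circadian clock and unfolded protein stress (0.959 each). At an unadjusted p under 0.05 these lists held 3, 1, 1, 4, 4, 1, 0, 0, 1, 2 and 4 members, and DESeq2 called 1, 1, 1, 2, 0, 1, 0, 0, 1, 0 and 2. Of these lists edgeR called 1 member, in NRF2 and oxidative stress, and 0 in the others. Adjusted over the list alone, 1 member rose in each of the stellate cell, cholangiocyte and NRF2 lists and 0 passed in the other 8. The median of the clock list lay just below 0 against a test direction of higher. Neutrophil markers had 4 of 12 members tested, with Csf3r higher (2.44 ± 0.36), adipose 4 of 9 and exocrine pancreas 2 of 12, too few for a list test.

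The number of genes called in the libraries labelled KO fell without each library in turn, least without KO replicate 1. It was 315, 323 and 305 without replicate 1, 2 or 3 of the libraries labelled wild type. Without replicate 1, 2 or 3 of those labelled KO it was 530, 124 and 178, and DESeq2 called 1244. Of 71 named genes called, 20 held in all 6 such fits and 51 were lost in at least 1, with the same sign throughout. Leaving out KO replicate 2 or 3 ended 49 or 45 calls, and the least settled, Itgax, Tfeb and Abcg8, were lost in each. Quantile normalization or the replicate block also ended the calls of Itgax and Tfeb, and a mean of at least 50 that of Cdh5.

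By its labels, the second comparison asks what injected lipid droplets change in a healthy liver. The libraries labelled LD had more of several male-biased and metabolic hepatocyte transcripts and less of matrix, cell cycle and lipid-associated macrophage transcripts. Hsd3b5 (chromosome 3, 98618634 to 98630252), a steroid dehydrogenase of male mouse liver, went from 69.1 ± 28.9 to 5175 ± 2570 normalized counts, a log2 fold change of 6.13 ± 0.41 (adjusted p = 0.000388). Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, went from 1670 ± 569 to 382 ± 14.5, a change of -2.07 ± 0.20 (adjusted p = 0.00277). Col1a1 (chromosome 11, 94936224 to 94953042), the main chain of type I collagen, went from 8230 ± 1105 to 4336 ± 325, a change of -0.92 ± 0.11 (adjusted p = 0.00428). Cd163 (chromosome 6, 124304656 to 124330527) went the other way from Gpnmb, from 19.6 ± 5.13 to 139 ± 37.7, a change of 2.76 ± 0.29 (adjusted p = 0.00293). As with Ms4a7 above, these directions belong to the labels.

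Of 14900 genes tested, 620 passed in the libraries labelled LD against those labelled PBS, 290 higher (46.8%) and 330 lower. Changes of at least 1 log2 unit numbered 99 rises and 156 falls, and 2933 genes had an unadjusted p under 0.05. The 3 values of a group lay apart from the 3 of the other for 25.4% of genes, where chance gives 10%. Next to Hsd3b5, the largest rises within the rule for named genes were in the protease inhibitor gene Serpina3h (4.65 ± 0.27), LOC118567843 (4.96 ± 0.49), and Mup-ps1, Mup11, Mup1, Mup15, Mup12, Mup17 and Mup14 (3.24 to 4.88). Serpina3h and the Mup genes belong to families of close copies that can share reads. Among the rises listed next to Hsd3b5, the call of Mup1 was lost without 1 library in 4 of 6 fits (adjusted p up to 0.0611). Besides Ms4a7, the largest falls within that rule were in Lrtm2 (-3.34), Sdcbp2 (-2.72), Tmem45a (-2.57), Sytl5 (-2.48), the epithelial transcription factor Ehf (-2.38), the fatty acid elongase Elovl7 (-2.22), Limch1 (-2.17), Mybl1 (-2.15) and Urml (-2.09). Of these, Sdcbp2 and Limch1 held without any 1 library, and the others were lost in at least 1 such fit with adjusted p up to 0.147.

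**Figure D3:**
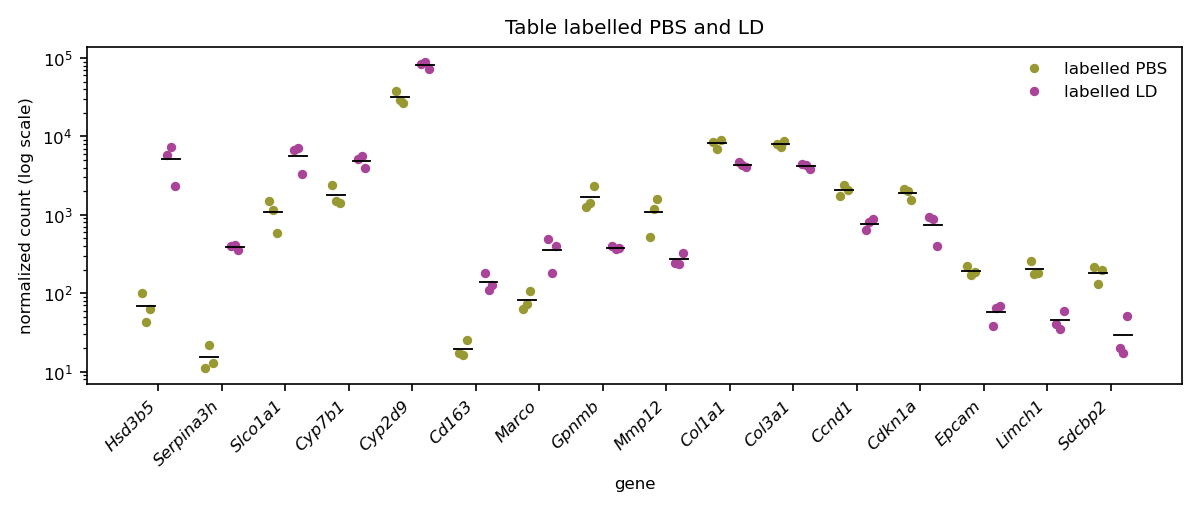
Normalized counts (log scale) of 16 named genes in the 6 libraries labelled PBS or LD; points are libraries and bars are means of 3. Hsd3b5 averaged 69.1 and 5175, Gpnmb 1670 and 382, and Col1a1 8230 and 4336 in the libraries labelled PBS and LD.

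Matrix and cell cycle transcripts fell together in the libraries labelled LD. Of 18 fibrosis and extracellular matrix genes, 13 fell and 5 did not pass (17 fell adjusted over the list alone, camera adjusted p = 7.94e-13, adjusted p = 0.283 with an estimated correlation). Besides Col1a1, Col3a1 fell by 0.91, Sparc by 0.73 and Col6a3 by 1.20, all without exception when 1 library was left out. Stellate cell markers, from the cells that make much of this matrix, did not fall as a list: 1 of 12 fell, Rgs5 (-0.53 ± 0.09), and 11 did not pass (5 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.157). Of 22 cell cycle genes, 8 fell and 14 did not pass (13 fell adjusted over the list alone, camera adjusted p = 3.98e-10, adjusted p = 0.315 with an estimated correlation). They included the cyclin Ccnd1 (-1.41 ± 0.15), Birc5 (-1.32 ± 0.21) and the mitotic activator Cdc20 (-1.16 ± 0.19). Of 15 p53 and cell death genes, 4 fell and 11 did not pass (8 fell adjusted over the list alone, camera adjusted p = 4.16e-05, adjusted p = 0.16 with an estimated correlation). The cell cycle inhibitor Cdkn1a (-1.43 ± 0.29) and Phlda3 (-1.30 ± 0.19) were the steepest of those named. Of 10 cholangiocyte markers, 4 fell and 6 did not pass (9 fell adjusted over the list alone, camera adjusted p = 7.99e-07, adjusted p = 0.16 with an estimated correlation). Epcam, an adhesion molecule of bile duct cells, stood at -1.76 ± 0.26 and the duct keratin Krt19 at -0.87 ± 0.20.

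Lipid-associated and monocyte lists were lower in the libraries labelled LD, and the Kupffer list did not pass. Of 16 lipid-associated macrophage markers, 8 fell and 8 did not pass (9 fell adjusted over the list alone, camera adjusted p = 4.32e-07, adjusted p = 0.357 with an estimated correlation). Besides Gpnmb, the lysosomal proton pump subunit Atp6v0d2 fell by 1.17 and the elastase Mmp12 by 1.89. Trem2, named here after its values were seen, went from 310 ± 122.8 to 134 ± 15.8 normalized counts (-1.15, adjusted p = 0.037). Of 13 Kupffer cell markers, Cd163, Marco (2.03 ± 0.36) and the ficolin gene Fcna (0.85 ± 0.16) rose and 10 did not pass (5 rose adjusted over the list alone). The Kupffer list median was -0.05 while its mean was 0.42 and its test direction was higher (camera adjusted p = 0.145). Of 15 monocyte and recruited macrophage markers, 3 fell and 12 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.000609, adjusted p = 0.357 with an estimated correlation): the chemokine receptors Cx3cr1 (-1.05 ± 0.13) and Ccr2 (-0.92 ± 0.16), and Lyz2 (-0.69 ± 0.16). Of 17 cytokines and chemokines, Cxcl1 (-0.76 ± 0.17) and Tgfb2 (-1.03 ± 0.24) fell and 15 did not pass (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00864, adjusted p = 0.357 with an estimated correlation). Of 12 danger and lipid receptors, the fatty acid receptor Cd36 fell (-0.53 ± 0.10) and 11 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.0478, adjusted p = 0.685 with an estimated correlation). Of 18 acute phase genes, 4 fell and 14 did not pass (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.691 with an estimated correlation). Among them were the siderophore binder Lcn2 (-0.77 ± 0.14) and Orm2 (-0.77 ± 0.15). Of 11 T and NK cell markers, Cd4 rose (2 ± 0.38) and 10 did not pass (2 rose adjusted over the list alone, camera adjusted p = 0.00905, adjusted p = 0.497 with an estimated correlation).

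Some hepatocyte lists were higher in the libraries labelled LD, while those of the acute phase (above) and of NRF2 and oxidative stress were lower. Of 22 genes of xenobiotic metabolism, 8 rose and 14 did not pass (13 rose adjusted over the list alone, camera adjusted p = 2.37e-05, adjusted p = 0.357 with an estimated correlation). Among them were Cyp2d9 (1.39 ± 0.15), Cyp1a2 (1.03 ± 0.12) and the glutathione transferase Gstp1 (0.94 ± 0.10). Of 15 hepatocyte markers, 2 rose and 13 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.000113, adjusted p = 0.357 with an estimated correlation). Among them was Hpd, of tyrosine breakdown (0.68 ± 0.12). Of 16 genes of bile acid synthesis and transport, 3 rose, 1 fell and 12 did not pass (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00325, adjusted p = 0.315 with an estimated correlation). The uptake transporters Slc10a1 (0.94 ± 0.11) and Slco1a1 (2.42 ± 0.36) and the hydroxylase Cyp7b1 (1.5 ± 0.20) rose, and the basolateral exporter Abcc4 fell (-1.82 ± 0.31). Of 12 sex-biased or sex chromosome genes, Hsd3b5, Cyp7b1 and Slco1a1 rose and 9 did not pass (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.497 with an estimated correlation). Of 12 genes of glucose production, Slc37a4 rose (0.54 ± 0.11) and 11 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.00413, adjusted p = 0.283 with an estimated correlation). Of 16 NRF2 and oxidative stress genes, 4 fell and 12 did not pass (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00407, adjusted p = 0.348 with an estimated correlation). They included the glutathione transferases Gstm3 (-1.18 ± 0.17) and Gsta1 (-1.85 ± 0.36). In the clock list limma and edgeR called 0 of 15 and DESeq2 2, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, at a median of 0.52 (camera adjusted p = 0.0313, adjusted p = 0.357 with an estimated correlation).

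The other lists did not pass in this comparison. In fatty acid synthesis 3 of 17 rose, the lipogenic regulators Mlxipl (0.57 ± 0.08), Thrsp (1.01 ± 0.18) and Srebf1 (0.65 ± 0.13) (4 rose adjusted over the list alone, camera adjusted p = 0.148). Among lipid droplet proteins Dgat2 rose (0.42 ± 0.09, 1 of 18, with 1 up and 1 down adjusted over the list alone, camera adjusted p = 0.762). In fatty acid oxidation the hormone gene Fgf21 fell (-1.04 ± 0.20, 1 of 23, 1 adjusted over the list alone, camera adjusted p = 0.755). Among immediate early genes Egr1 fell (-0.81 ± 0.17, 1 of 15, 1 adjusted over the list alone, camera adjusted p = 0.917). Limma and edgeR called 0 of 16 NLRP3 inflammasome genes and DESeq2 1, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone, at a median of -0.08 (camera adjusted p = 0.531). Limma likewise called 0 members of the lists of dendritic cells and MHC class II (camera adjusted p = 0.126), neutrophils (0.157), adipose tissue (0.252), unfolded protein stress (0.256), the lysosome (0.452), the MS4A cluster (0.452), the interferon response (0.483), B and plasma cells (0.516), cholesterol synthesis (0.766), sinusoidal endothelium (0.859) and red blood cells (0.893). At an unadjusted p under 0.05 these lists held 4, 2, 4, 2, 4, 2, 1, 0, 3, 1 and 1 members, and DESeq2 called 3, 0, 0, 1, 2, 0, 0, 0, 1, 1 and 1, while edgeR called 0 in each. Adjusted over the list alone, 1 member fell in the neutrophil list, 1 rose in each of the adipose, endothelium and red blood cell lists, and 0 passed in the other 7. With 1 of 12 exocrine pancreas genes tested (Cela1, 0.88 ± 0.20) and 2 of 15 mitochondrially encoded transcripts, those lists were not tested.

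The count of 620 moved without each library in turn. It was 404, 134 and 171 without replicate 1, 2 or 3 of the libraries labelled PBS, and 243, 212 and 1226 without replicate 1, 2 or 3 of those labelled LD, and DESeq2 called 1193. Of 78 named genes called, 28 held in all 6 such fits and 50 were lost in at least 1, with the same sign throughout. Leaving out PBS replicate 2 or 3 ended 46 or 44 calls. Quantile normalization ended 11 named calls, among them those of Ehf, Krt19, Cxcl1, Dgat2, Thrsp, Srebf1, Slc37a4 and Abcg8. The call of Tgfb2 was lost with it, in edgeR, without a filter and with a mean of at least 50.

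**Figure D4:**
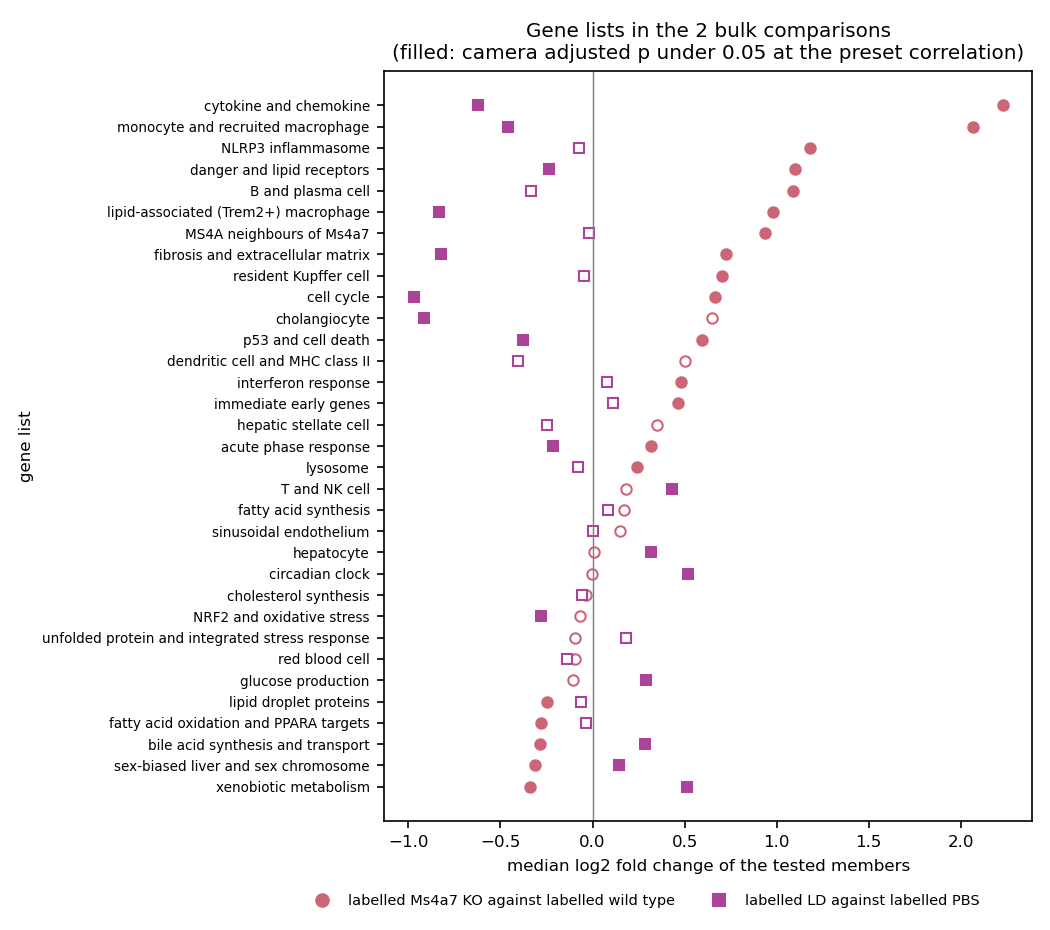
Median log2 fold change of each gene list tested in both bulk comparisons, with circles for labelled KO against labelled wild type and squares for labelled LD against labelled PBS; filled symbols have a camera adjusted p under 0.05 at the preset correlation. Lists past that threshold numbered 20 of 34 and 17 of 35, and 0 in either with an estimated correlation.

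Across both comparisons, 20 of 34 lists passed for the libraries labelled KO (15 higher, 5 lower) and 17 of 35 for those labelled LD (7 higher, 10 lower). Other splits of the same 6 libraries gave up to 23 and 18 lists. These counts therefore do not set the labelled groups apart from other groupings. With an estimated correlation camera called 0 lists in either, with lowest adjusted p of 0.157 and 0.16 and with 9 and 5 lists at an unadjusted p under 0.05, while fry called 12 and 11.

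By the labels, the third comparison asks whether the genes that move with lipid droplets are those that move with loss of Ms4a7. Across 13188 genes tested in both tables the fold changes tended in part to run in opposite directions, with Spearman's rho -0.33 and Pearson's r -0.30. Genes are not independent replicates, so no p is given. Of the genes higher in the libraries labelled KO, 26 were lower in those labelled LD, where 8.89 would be shared by chance (Fisher's exact test, 2-sided, adjusted p = 1.91e-06 over 4 overlaps). That test treats genes as independent, which they are not, so its p values are not exact. They included Ms4a7, the elastase Mmp12, Ccnd1, Mki67, Lgals3 and Cd9. Of the genes lower in the libraries labelled KO, 14 were higher in those labelled LD, against 2.02 by chance (adjusted p = 5.04e-08), with Mup1, Mup12, Mup19, Slc10a1 and Ces3b among them. Genes higher in both were Marco, Cd163 and Abcg8, a sterol exporter subunit (3, against 9.15 by chance, adjusted p = 0.0516), and 0 were lower in both (1.96 by chance, adjusted p = 0.27, with 0 in edgeR and 4 in DESeq2). These genes of the opposed overlaps, beyond those named before, were picked after their values were seen. The 26 became 11, 11, 8 and 10 without wild type replicate 2 or 3 or KO replicate 2 or 3, 3 and 4 without PBS replicate 2 or 3, and 6, 5 and 61 without LD replicate 1, 2 or 3. In the same order the 14 became 6, 6, 6 and 9, then 3 and 7, then 3, 3 and 33. The 3 higher in both became 1 without wild type replicate 2, any 1 of the KO replicates, PBS replicate 1 or LD replicate 1, and the 0 lower in both became 2 without wild type replicate 2 or LD replicate 3. In DESeq2 these overlaps were 115 and 73, with 14 genes higher in both.

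The single-nucleus table gives the mean level of 21915 genes in 12 numbered groups of nuclei for each genotype, 10 of which could be named from marker genes. The nuclei behind each mean are not given and each genotype has 1 library, so there is no replicate error, no test and no counting interval. How doublets were treated is not stated, and means do not allow their removal. In the macrophage-like group Ms4a7 was 1.25 UMIs per 10000 in wild type and 0.622 in KO, a ratio of 0.5, so the transcript was lower but present under the KO label. It was listed at 0 in both genotypes in the T or NK cell-like and B cell-like groups. Lipid-associated macrophage genes were lower in KO in that group: Trem2 went from 0.479 to 0.247, Gpnmb from 3.45 to 1.67, Mmp12 from 4.29 to 1.55 and Atp6v0d2 from 1.89 to 0.440. The median log2 ratio of this list was -0.35 over 14 members, at percentile 0 of 10000 random lists of matched level, with 9 below 0 and 5 above. Kupffer cell genes were higher in KO, at a list median of 0.68 (percentile 100, 12 of 13 above 0), as Clec4f went from 4.56 to 9.10, Cd163 from 0.527 to 3.26 and Marco from 0.188 to 0.761. The NLRP3 inflammasome list had a median of 0.45 (percentile 100, 14 of 16 above 0) and the interferon list 0.41 (percentile 99.9, 16 of 16 above 0). Albumin, a hepatocyte transcript, was also higher in this group in KO (7.84 and 17.3, a ratio of 2.20), and in each of the 12 groups, by ratios of 1.17 to 2.89.

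**Figure D5:**
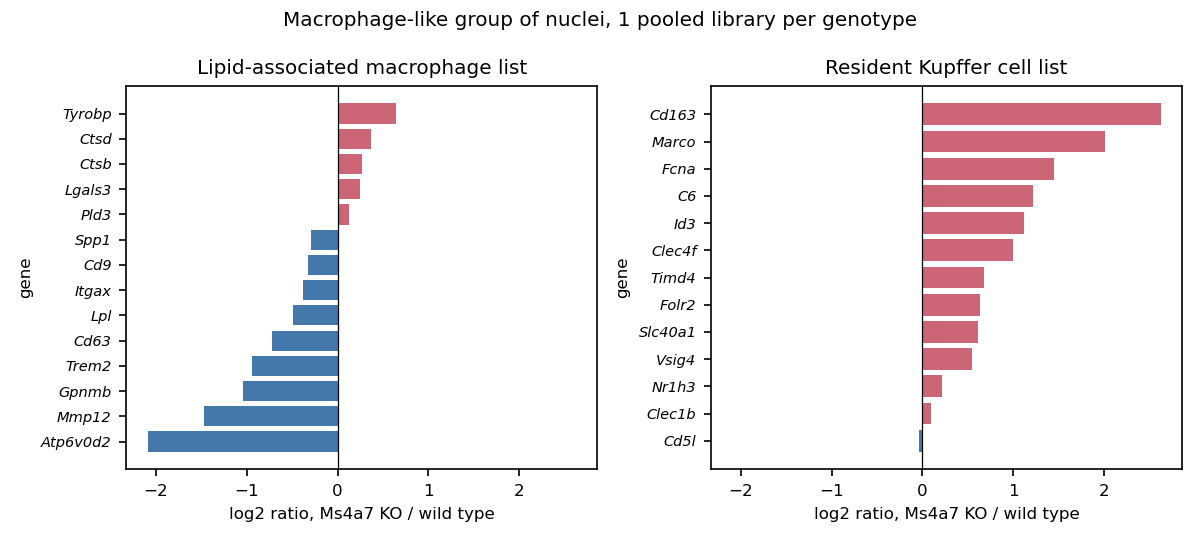
Log2 ratio of KO to wild type for lipid-associated macrophage genes and Kupffer cell genes in the macrophage-like group of nuclei; bars are single genes from 1 pooled library per genotype, without error. The list medians were -0.35 and 0.68, and Cd163 stood at 2.62.

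In the stellate cell-like group the fibrosis list was lower in KO, at a median log2 ratio of -0.54 (percentile 0, 11 of 17 below 0): Col1a1 went from 1.43 to 0.737, Col6a3 from 6.65 to 2.74 and Dpt from 0.567 to 0.241. The contractile gene Acta2 was higher (0.148 to 0.443), as were the 12 members of the stellate cell list (median 0.36, percentile 100), while Pdgfrb, a stellate marker counted in the fibrosis list, went from 4.01 to 2.75. In the same group mitochondrially encoded transcripts were higher in KO (median 0.35, percentile 99.8, 12 of 13 above 0), with mt-Co1 from 10.3 to 15.2. Immediate early genes were also higher (0.83, percentile 99.9, 8 of 8), with Jun from 0.0889 to 0.35. So were hepatocyte genes (1.01, percentile 100, 14 of 15), but not only in this group. Serpina1c was higher in KO in every group, as in the B cell-like group (1.58 to 7.51). Whether nuclei of other cell types made these hepatocyte transcripts was not tested. The mitochondrial list was also above the central 95% in both hepatocyte-like groups (0.31 and 0.54), the endothelial cell-like group (0.20) and both unnamed groups (0.64 and 1.04), and stood at -0.18 in the macrophage-like group (percentile 2.82). In the endothelial cell-like group the sinusoidal endothelium list was higher in KO (median 0.36, percentile 100, 11 of 14 above 0) and Col8a1, Thsd7a and the lymphatic growth factor Vegfc were lower, Vegfc from 5.60 to 1.55. Both hepatocyte-like groups had higher Serpina3k, Thrsp and Serpina1c in KO and lower Erbb4 and Rad51b. In the first of them Serpina3k went from 0.891 to 6.73 and Erbb4 from 13.2 to 2.77. The sex-biased list was higher in KO in both (medians 0.84 and 1.62, percentile 100 each): Hsd3b5 went from 0.0505 to 1.47 and from 0.0128 to 0.753, and Slco1a1 had ratios of 2.76 and 6.68. Their hepatocyte lists had medians of 0.70 and 0.95, their NRF2 lists -0.30 and -0.54, their fatty acid synthesis lists 0.17 and 0.38, and their fatty acid oxidation lists -0.21 and -0.26, all outside the central 95% of random lists. Over all groups, 97 of 291 list medians (33.3%) lay outside that range. They include the hepatocyte, acute phase and sex-biased lists in groups named for other cell types. Whether those medians reflect the named cell types was not tested.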

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

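The alternatives named TMM and edgeR, and no others here, were chosen after the results were seen. For the libraries labelled KO against wild type, the count of 589 genes became 1244 in DESeq2, and 124 to 530 when 1 library was left out. For those labelled LD against PBS, 620 became 1193 in DESeq2, 255 with a log2 change of at least 1, which is a stricter criterion by construction, and 134 to 1226 when 1 library was left out. The cause of the DESeq2 and leave-out differences was not tested. The other counts stayed within 1.5 times: 450 to 822 for KO (quantile, no filter, mean of at least 50, pseudocount 5, block, log2 change of at least 1, edgeR 648 and TMM 616) and 532 to 793 for LD (the same without the log2 minimum, edgeR 601 and TMM 614). The highest of each is the replicate block, although replicate numbers did not pair libraries (correlations of -0.03 to 0.119 and -0.043 to 0.132 between same-numbered libraries). Lists past the threshold, 20 and 17, became 0 and 0 with an estimated correlation and 12 and 11 in fry, and 18 to 24 and 16 to 18 without 1 library. The correlation between comparisons stayed negative, from -0.369 to -0.273 without 1 library. Among named genes 1 changed sign, uncalled Cela1 for KO (-0.188), which ran from -0.432 to 0.051 without 1 library and was above 0 without wild type replicate 2 or KO replicate 3. Of nuclei list medians outside the central 95%, xenobiotic metabolism in the second hepatocyte-like group changed from 0.181 to -0.033 with a stricter level floor, and the cause was not tested. Neither quantile nor TMM scaling changed the sign of a named gene. Depth limits ratios of genes with few reads, such as Acod1 (3 reads under the wild type label, interval 73.7 to 1050).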

Other observations

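The tests of sums of Mup and Y-linked genes, of macrophage and endothelial lists, and of labels that are right or exchanged within 1 table were chosen after the results were seen, and those of exchanged table descriptions, of DNA near Ms4a7 and of other splits before. In the neutrophil-like group of nuclei the precursor genes Ngp (0.254 to 9.47 UMIs per 10000) and Camp (0.0846 to 2.30) were higher in KO, beside a median log2 ratio of 0.56 for the neutrophil list (percentile 97.8). In a dendritic cell-like group the interferon list had a median of 1.08, with 10 of 10 members above 0, and the migratory marker Fscn1 went from 2.62 to 0.481. In the cholangiocyte-like group Igkc went from 0.12 to 3.76 and Ighg2c, listed at 0 in wild type, was at 2.35 in KO, both transcripts of antibody-secreting cells. One unnamed group held haemoglobin transcripts in KO, with Hbb-bs at 0.925 in wild type and 79.2 in KO. The other unnamed group held a Kupffer list median of 0.75 and a lipid-associated list median of -0.66. Each of these rests on 1 pooled library per genotype with doublets not assessed, and albumin was higher in KO in every group. The nuclei behind each mean are not given. Over genes above the level floor, log2 ratios had quartiles of -0.714 and 0.861 in the neutrophil-like group. They were -0.547 and 0.598 in the group with haemoglobin transcripts, and -0.186 and 0.285 in the first hepatocyte-like group.

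The first pattern is Ms4a7 against the genotype labels, where the submitters' names of the 2 bulk tables also disagree with the labels. If the descriptions of the tables were exchanged, the table labelled PBS and LD would follow the KO to wild type ratios of the hepatocyte-like nuclei more closely than the other, and it did: rho was 0.449 against -0.089 across 9285 genes, a difference of 0.538 (SE 0.0159 over resampled genes, which are not independent), though only 0.14 against 0.093 in macrophage-like nuclei. An exchange of wild type and KO within their own table needs NASH-diet livers there, but fibrosis genes relative to hepatocyte genes lay lower in each of those 6 libraries than in any labelled PBS or LD, by -2.67 on average (log2, tables counted separately), although the sign of the -0.089 goes with it. Correct labels need NASH-diet livers there too, so the same -2.67 argues against them. The libraries labelled wild type or KO ran from -10.866 to -9.407, and those labelled PBS or LD from -8.183 to -6.851. The 2 earlier tests had left correct labels open: the lipid-associated list relative to hepatocyte genes (-1.38, overlapping ranges) and the rho above (-0.089 against them, 0.093 for them). An exchange of descriptions would make the second comparison KO against wild type on the NASH diet and the first LD against PBS. Of the explanations weighed here, it alone is not argued against by these values. It stays a candidate, since the tables were counted separately and the deposited data do not settle it.

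The second pattern is the rise of Mup and male-biased genes in the libraries labelled LD. Reads moved between close copies would leave their sum unchanged, but the sum over 38 Mup genes changed by 0.9 (log2, SE 0.2). Animals of another sex in 1 group would change Y-linked reads, whose sum over 4 genes differed by 0.07 (SE 0.057) and was above 0 in all 6 libraries. DNA carried along near a targeted Ms4a7 that acted only on genes beside it would put most of the rising genes near it. Of 275 rising genes, 2.18% (SE 0.88) lay within 20 Mb, against 2.13% of genes tested. Genes near Ms4a7 could also act on distant ones, so this share does not exclude such DNA. A biological difference in treatment or genotype stays open as a hypothesis found on these data, and in the hepatocyte-like nuclei, which compare KO with wild type, Hsd3b5 (ratios of 29 and 57.8), Mup7 (31.9 and 68.8), Slco1a1 (2.76 and 6.68) and Elovl3 (3.71 and 7.16) were higher in KO too, from 1 pooled library each.

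The third pattern is lower lipid-associated macrophage genes beside higher Cd163 and Marco in the libraries labelled LD. Fewer macrophages of every kind would lower both lists alike. The mean of the Kupffer list lay above that of the lipid-associated list by 1.25 (log2, SE 0.31 over list genes). Without Cd163 and Marco, which are part of the pattern, the gap was 0.89 (SE 0.2 over list genes). A larger share of hepatocyte RNA would lower endothelial genes as much. Their list mean lay above that of the lipid-associated list by 0.85 (SE 0.158 over list genes). These SE treat genes of the same libraries as independent and leave out the spread between livers. They therefore exclude neither explanation. Without Cd163 and Marco the Kupffer list mean was 0.06, so a gain of resident macrophages would rest on few genes. Cells were not counted by type, and a change in the mixture or state of macrophages stays open and untested.

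With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of the table labelled wild type and KO gave 589 genes and the highest other 13, so 1 of 10 was as large. In the table labelled PBS and LD these were 620 and 1, again 1 of 10. For lists, 3 of 10 splits reached the real 20 (highest other 23) and 2 of 10 the real 17 (highest other 18). The number of lists past the threshold thus does not set the real split apart in either table.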
